A study of Mus musculus with 40 samples.

How the data were processed

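The series holds 40 RNA-seq libraries of mouse hypothalamus in 20 groups of 2 libraries. Each library was made from punches 2 mm wide, pooled from 4 mice, that held either the arcuate nucleus (ARC) or the anteroventral periventricular nucleus and the surrounding preoptic area (AVPV, also called RP3V). Both nuclei hold neurons that make kisspeptin from the Kiss1 gene. Ribosomes of these neurons carried an HA tag on the ribosomal protein Rpl22, and an antibody to HA pulled them down with the RNA bound to them. The RNA that came down is called IP here, and RNA from a saved part of the same lysate is called input. The tag was delivered in either of 2 ways. In RiboTag mice a Kiss1-Cre allele switched on the tag from the genomic Rpl22 locus, so any cell that ever made Cre carries it. In AAV mice a virus with a Cre-dependent tagged Rpl22 was injected into 1 of the nuclei of adult Kiss1-Cre mice. The RiboTag groups are intact female, intact male and castrated male, and the AAV groups are female and male, each for both nuclei and for IP and input. One AAV female AVPV IP library has a label that names ARC as its target, while its title and tissue name AVPV, and it was kept in the AVPV group.

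Per the labels, cDNA came from the NuGEN Ovation RNA-Seq V2 and Ultralow kits and was read on a NextSeq500 for 75 cycles from one end. The strand is not stated. The submitters' processing notes name bcl2fastq 2.20.0.422, TopHat2 2.1.1, Cufflinks 2.2.1, Cuffnorm and Cuffdiff, and the genome build mm10. The deposited table, made by the authors with Cuffdiff, gives for each gene and library the raw fragment count and the FPKM (fragments per kilobase, scaled to depth). The deposited raw fragment counts are expected counts that share reads between transcripts, and 91% of the values lay within 0.01 of a whole number. The authors' FPKM were used for alternatives only. Libraries were read from the replicate numbers of the table, which run from 0 while those of the labels run from 1. The same order was assumed, so which library of a group is replicate 1 and which is replicate 2 rests on that assumption. Each library has 24829 lines for 24358 gene symbols. Lines of the 259 symbols with more than 1 line were summed. Rn45s and Lars2, masked by Cuffdiff for their depth in 30 values, were left out, and they take up to 13.06% of a library's fragments. The 63 values of 29 genes that Cuffdiff marked as failed were kept. No mitochondrial symbols are present, so no share of mitochondrial RNA could be given.

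Counts were rounded and tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr with its default minimum count of 10, and the quasi-likelihood test with robust dispersion, with 1 mean per group. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. With 2 libraries per group the spread was shared over groups fitted together: the 24 RiboTag libraries or the 16 AAV libraries for IP against input, the 12 RiboTag IP, 8 AAV IP or 12 RiboTag input libraries for region, sex and castration, and all 20 IP libraries for AAV against RiboTag. There were 21 comparisons. Adjusted p-values below are from edgeR's test unless another tool is named, and they reflect spread between pools of mice, not between single mice. CPM are counts scaled to library size with TMM factors. Errors of log2 fold changes are standard errors, and errors of CPM are SD.

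Before the data were examined, 30 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists hold Kiss1 neuron genes (a core set, a KNDy set for the arcuate neurons that also make neurokinin B and dynorphin, and a set of genes known from AVPV Kiss1 neurons), dopamine, GABA and glutamate genes, receptors, channels, peptide systems, regional transcription factors, immediate early and interferon genes, sex chromosome genes, and markers of other neurons, glia, vessels, tanycytes, pituitary, choroid plexus and blood. Each list with at least 3 measured members was tested with camera of limma 3.58.1 on log2 CPM at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Per list, calls were counted after adjustment over all genes and adjusted over the list alone. The named genes are 13 core genes, per direction the 6 with the largest fold among called genes with at least 5 CPM in the higher group and libraries that do not overlap (unnamed models, small RNAs and sex chromosome genes excepted), and up to 2 members per direction of each list described. Some genes that this rule names are not reported here. Where a side had 0 counts, the fold is given as a bound against 3 counts over the whole group. Where it had 1 to 3 counts, the ratio is given with an exact 95% counting interval. Such bounds and intervals cover counting error only.

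Alternatives were DESeq2 1.42.0, RLE factors, no filter, limma-trend on log2(FPKM + 1), all 40 libraries in a single fit, a block for the replicate number, each library left out in turn, and, for lists, pseudocounts of 1 and 0.1 on FPKM. A further alternative, without the 3 libraries with the fewest detected genes, was chosen after seeing the data. The tests were tried on simulated data with the spread of each fit and 200 changed genes per comparison. Of 4-fold changes, 71.6% were recovered for IP against input in RiboTag ARC, 52.5% for AVPV against ARC in RiboTag IP and 27.1% for castration in ARC IP, where 65.2% of 8-fold changes were recovered. False calls were 10 of 101 for AVPV against ARC in RiboTag IP in edgeR and 55 of 178 by DESeq2, so a call by DESeq2 alone is weak support. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

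Gene positions are from GENCODE M21 on GRCm38, the assembly of mm10, with 126 of 127 named symbols matched. Since the strand of the reads is not stated, fragments of genes that overlap were not separated further: 34 named genes share exonic bases with a gene on the opposite strand and 12 with one on the same strand. Kiss1 (chromosome 1, 133321875 to 133329901) lies within read-through transcripts that join it to Golt1a. Pmch and Parpbp share exonic bases on opposite strands, so their values are not independent. Kiss1 itself was shallow, at 0 to 37.2 CPM, in libraries of 3179974 to 21888881 counts, so its folds are imprecise.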

Results

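The data are RNA-seq counts of RNA bound to tagged ribosomes of Kiss1 neurons (IP) and of whole tissue (input) from the mouse hypothalamus. Kiss1 encodes kisspeptin, the peptide that drives neurons making gonadotropin-releasing hormone. Its neurons sit in the ARC, where many also make neurokinin B (Tac2) and dynorphin (Pdyn), and in the AVPV, where many make the dopamine-forming enzyme tyrosine hydroxylase (Th). The 40 libraries form 20 groups of 2: RiboTag female, male and castrated male, and AAV female and male, each for ARC and AVPV and for IP and input. Every library is a pool of 4 mice. The labels name the expression of Kiss1 neurons in both nuclei and both sexes as the subject. Castration removes the main source of testosterone. Total counts per library ran from 5119858 to 21888881 in RiboTag IP and from 3179974 to 9002057 in RiboTag input. They ran from 5922902 to 18248701 in AAV IP and from 4962468 to 9946812 in AAV input. Detected genes ran from 13485 (castrated male ARC IP replicate 2) to 18018.

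Kiss1 itself stayed at low counts. In RiboTag ARC IP it stood at 5.49 and 2.78 CPM in the female libraries, 0.133 and 1.69 in the male ones and 13.5 and 37.2 in the castrated male ones. In RiboTag AVPV IP it stood at 12.3 and 7.39 CPM in females, 1.11 and 3.19 in males, and 0.556 and 0 in castrated males. In AAV IP it reached 5.02 and 0.144 CPM in female ARC, 0 and 0.467 in male ARC, 12.8 and 8.05 in female AVPV and 1.95 and 1.16 in male AVPV. No input library exceeded 0.718 CPM of Kiss1.

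**Figure D1:**
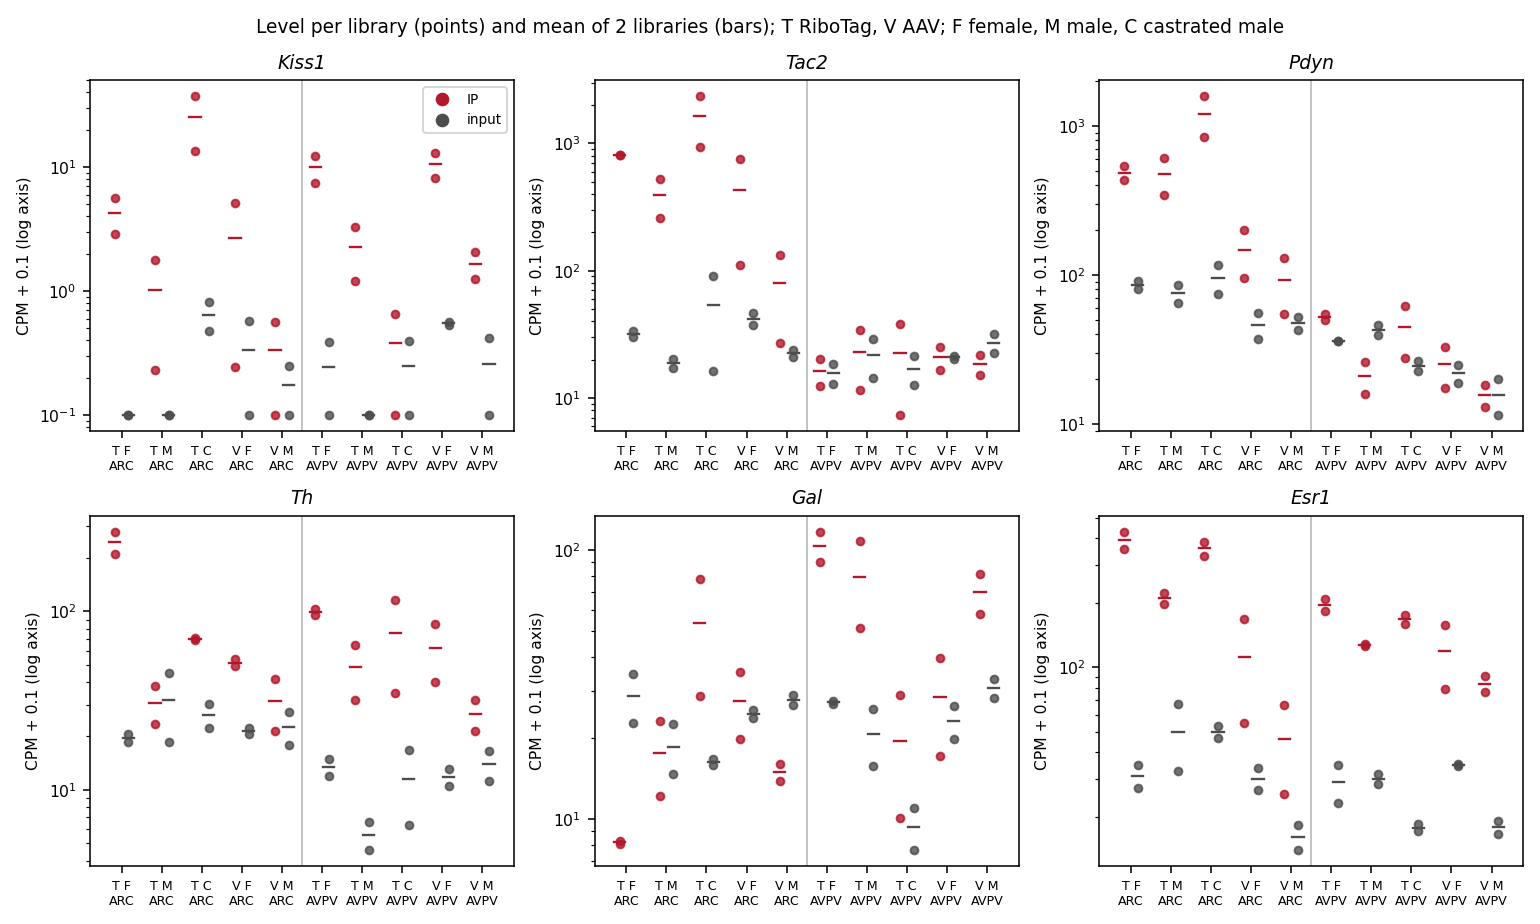
Level of Kiss1, Tac2, Pdyn, Th, Gal and Esr1 in every library, as TMM-normalised CPM plus 0.1 on a log axis, for IP (red) and input (grey) of each group, with points for libraries and bars for the mean of 2 libraries. Tac2 and Pdyn stand above input in RiboTag ARC IP and near input in AVPV IP, and Kiss1 in ARC IP is highest in castrated males, at 13.5 and 37.2 CPM.

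The first question was which transcripts tagged ribosomes of the RiboTag ARC carried beyond their tissue. Genes of ARC Kiss1 neurons were far higher in IP than in input, over female, male and castrated male libraries together (n = 6 libraries a side, CPM as mean ± SD). Kiss1 (chromosome 1, 133321875 to 133329901) was at log2 fold change 6.55 ± 1.26, adjusted p = 0.00289, 9.85 ± 13.7 against 0.177 ± 0.294 CPM. Tac2 (chromosome 10, 127724478 to 127731768), for neurokinin B, was at log2 fold change 4.67 ± 0.45, adjusted p = 1.54e-06, 926 ± 705 against 33.9 ± 27.9 CPM. Pdyn (chromosome 2, 129686565 to 129699844), for prodynorphin, was at log2 fold change 2.94 ± 0.23, adjusted p = 2.5e-08, 705 ± 438 against 83.5 ± 17.4 CPM. Tacr3 (chromosome 3, 134829007 to 134934579), the receptor of neurokinin B, was at log2 fold change 3.55 ± 0.31, adjusted p = 1.46e-07, 237 ± 238 against 16.7 ± 12.2 CPM. The transcription factor Nhlh2 (chromosome 3, 102010076 to 102015492) had 4.18 ± 0.5, adjusted p = 1.32e-05. The core list of Kiss1 neurons had 6 of 7 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 3.41e-10, adjusted p = 0.012 with an estimated correlation). The KNDy list had 6 of 7 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 5.39e-12, adjusted p = 0.00517 with an estimated correlation).

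Receptors for sex steroids and prolactin were also higher in RiboTag ARC IP. The estrogen receptor Esr1 (chromosome 10, 4611593 to 5005614) was at log2 fold change 2.86 ± 0.19, adjusted p = 1.95e-09, 313 ± 90 against 42.5 ± 14.6 CPM. The prolactin receptor Prlr (chromosome 15, 10177238 to 10349180) was at log2 fold change 2.42 ± 0.21, adjusted p = 1.46e-07, 1055 ± 371 against 196 ± 54.2 CPM. The progesterone receptor Pgr rose less (1.13 ± 0.19, adjusted p = 0.000696). Their list had 4 higher and 1 lower of 8 over all genes, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.00076, adjusted p = 0.0395 with an estimated correlation). The ghrelin receptor Ghsr, Th and the glutamate transporter Slc17a6 rose as well (0.8 to 2.95, adjusted p from 0.00221 to 0.00742). The GABA transporter Slc32a1, Gal (for galanin), Penk (for enkephalin) and the tagged gene Rpl22 did not pass (-0.9 to 0.12, adjusted p from 0.0775 to 1), but Rpl22 did by DESeq2 (0.0118), with all 40 libraries in a fit (0.00231) and on FPKM (0.0358). Outside the lists, Lhfpl1, Fam159a and Etl4 were among the largest rises (3.86 to 5.24, adjusted p from 1.42e-09 to 0.0143). The tuberal transcription factors Tbx3 and Nkx2-1 rose (0.92 to 1.59, adjusted p from 0.0104 to 0.0133). The pacemaker channel list had 1 higher and 0 lower of 13 over all genes, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.0379, adjusted p = 0.17 with an estimated correlation). Immediate early genes, which follow neuronal activity, had 2 of 10 higher over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00716, adjusted p = 0.101 with an estimated correlation).

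Glia and other neurons were depleted from RiboTag ARC IP. The astrocyte glutamate transporter Slc1a2 was at log2 fold change -2.43 ± 0.29, adjusted p = 1.26e-05, 995 ± 412 against 5295 ± 833 CPM. The water channel Aqp4, the myelin gene Mbp and the microglial genes Cx3cr1 and Ctss fell (-4.41 to -2.13, adjusted p from 1.21e-07 to 0.00336). Astrocyte markers had 8 of 10 lower over all genes and 9 adjusted over the list alone (camera adjusted p = 3.41e-10, adjusted p = 0.101 with an estimated correlation). Oligodendrocyte markers had 8 of 10 lower over all genes and 9 adjusted over the list alone (camera adjusted p = 1.45e-10, adjusted p = 0.03 with an estimated correlation), and those of their precursors 4 of 6 lower over all genes and 5 adjusted over the list alone. Microglial markers had 5 of 10 lower over all genes and 9 adjusted over the list alone (camera adjusted p = 4.93e-07, adjusted p = 0.0856 with an estimated correlation). Peptide genes of other hypothalamic neurons fell too, among them Oxt (oxytocin), Pmch (melanin-concentrating hormone), Trh, Ghrh and Pomc (-4.02 to -1.9, adjusted p from 3.24e-05 to 0.0441). The other neuropeptide list had 0 higher and 5 lower of 12 over all genes, and 1 and 6 adjusted over the list alone (camera adjusted p = 0.000212, adjusted p = 0.012 with an estimated correlation). Islr and the transcription factors Gsx1, Ebf1 and Lhx2 had the largest falls (-6.33 to -5.81, adjusted p from 0.00021 to 0.0072).

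Of 16467 genes, 574 were higher and 670 lower in RiboTag ARC IP. The count of 1244 was 696 and 628 without female ARC IP replicate 1 or 2, and 718 and 703 without female ARC input replicate 1 or 2. It was 2380 without castrated male ARC IP replicate 1. Named calls that ended in leave-one-out runs, with the number of runs and the highest adjusted p, were Fam159a (4 of 12, up to 0.0721), Tbx3 (1 of 12, up to 0.0519) and Pomc (10 of 12, up to 0.132). Without the 3 libraries with the fewest detected genes, those of Nkx2-1 (0.0644), Trh (0.138), Tbx3 (0.0686) and Pomc (0.0518) ended.

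In the RiboTag AVPV the same question gave other peptides (n = 6 libraries a side). Th (chromosome 7, 142892752 to 142931128) was higher in IP at log2 fold change 2.93 ± 0.34, adjusted p = 2e-05, 72.6 ± 34.8 against 9.88 ± 4.98 CPM. Esr1 was at log2 fold change 2.69 ± 0.19, adjusted p = 1.14e-08, 160 ± 30.6 against 25 ± 6.97 CPM. Gal (chromosome 19, 3409915 to 3414544) was at log2 fold change 1.65 ± 0.35, adjusted p = 0.00871, 66 ± 42.8 against 18.5 ± 8.48 CPM. Penk (chromosome 4, 4133531 to 4138819) was at log2 fold change 1.24 ± 0.24, adjusted p = 0.00439, 530 ± 193 against 224 ± 31.2 CPM. Slc18a2, the vesicular monoamine transporter, and Cartpt, for the CART peptides, rose (1.37 to 2, adjusted p from 3.62e-05 to 0.00642). Kiss1 was at log2 fold change 4.54 ± 1.25, adjusted p = 0.0596, 3.98 ± 4.68 against 0.0955 ± 0.148 CPM, and did not pass over all genes, but did by DESeq2 (0.00828), with all 40 libraries in a fit (0.0239), with no filter (0.0142), on FPKM (0.00284) and without the 3 libraries of fewest detected genes (0.0365). Tac2 and Pdyn stood near input (0.13 to 0.19, adjusted p from 0.917 to 0.952), and Tacr3 was lower (-1.1 ± 0.29, adjusted p = 0.0459). The list of genes known from AVPV Kiss1 neurons had 7 of 11 higher over all genes and 9 adjusted over the list alone (camera adjusted p = 4.06e-14, adjusted p = 0.00969 with an estimated correlation). The core list had 4 higher and 1 lower of 7 over all genes, and 5 and 1 adjusted over the list alone (camera adjusted p = 9.59e-07, adjusted p = 0.0323 with an estimated correlation). The KNDy list was not called, with 0 higher and 1 lower of 7 over all genes, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.0896). Dopamine genes had 3 of 8 higher over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00356, adjusted p = 0.0942 with an estimated correlation). Opioid genes had 1 of 8 higher over all genes and 1 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.115 with an estimated correlation), and metabolic hormone receptors 1 of 11 higher over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0344, adjusted p = 0.0942 with an estimated correlation).

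Further genes higher in RiboTag AVPV IP were the synaptic vesicle gene Unc13b, Etl4, Ppp1r17, the spectrin gene Sptb, Prlr, Pgr, Ghsr and Nkx2-1 (0.81 to 3.8, adjusted p from 3.39e-08 to 0.0421). Of the GABA receptor subunits, Gabra2 rose (0.88 ± 0.2, adjusted p = 0.0135), while Gabrb2 fell (-0.98 ± 0.15, adjusted p = 0.00075), and their list was not called (camera adjusted p = 0.842). Slc32a1 did not pass (0.33 ± 0.2, adjusted p = 0.555). The glial genes Slc1a2, Aqp4 and Mbp fell (-2.25 to -1.75, adjusted p from 5.63e-08 to 0.0071). So did Slc18a3 (the vesicular transporter of acetylcholine), Sox21, the chaperone Cryab, Oxt and Rpl22 (-6.53 to -1.29, adjusted p from 0.000421 to 0.0449). Blood markers had 0 of 6 lower over all genes and 1 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.0813 with an estimated correlation).

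Of 16467 genes, 158 were higher and 249 lower in RiboTag AVPV IP. The count of 407 was 210 and 225 without female AVPV IP replicate 1 or 2, and 248 and 205 without female AVPV input replicate 1 or 2. It was 262 without male AVPV IP replicate 1, 229 and 249 without male AVPV input replicate 1 or 2, and 248 and 246 without castrated male AVPV input replicate 1 or 2. Named calls that ended in leave-one-out runs were Pgr (7 of 12, up to 0.11), Gal (2 of 12, up to 0.0516), Tacr3 (10 of 12, up to 0.182), Rpl22 (8 of 12, up to 0.109), Slc18a3 (6 of 12, up to 0.0641), Sox21 (3 of 12, up to 0.0628), Oxt (9 of 12, up to 0.184), Gabra2 (4 of 12, up to 0.0709) and Ghsr (10 of 12, up to 0.185). On FPKM those of Tacr3 (0.124) and Ghsr (0.0625) ended.

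**Figure D2:**
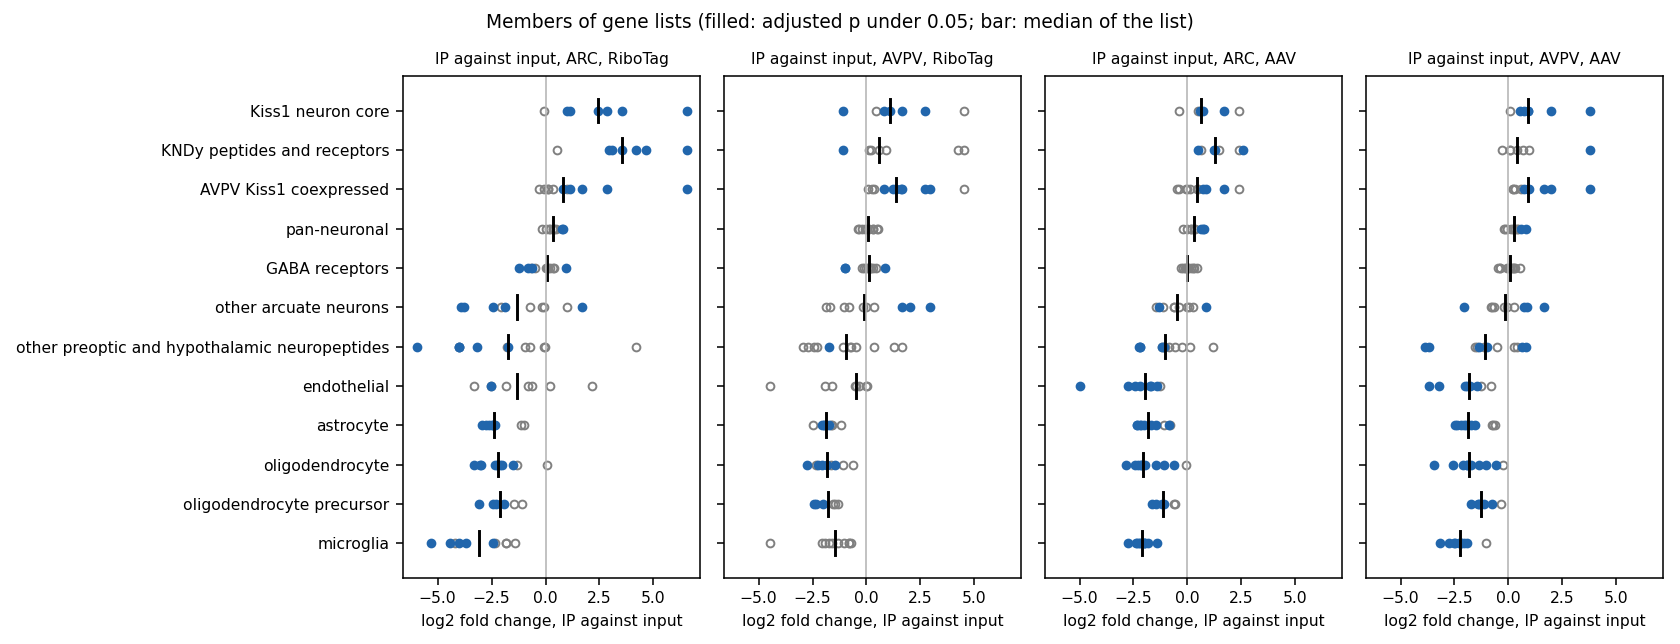
Log2 fold change of IP against input for each measured member of 12 gene lists, in RiboTag ARC, RiboTag AVPV, AAV ARC and AAV AVPV, with filled points for adjusted p under 0.05, open points for the others and a bar at the list's median. The KNDy list has a median of 3.55 in RiboTag ARC and 0.56 in RiboTag AVPV, and the astrocyte list lies at -2.41, -1.86, -1.84 and -1.85 in the order of the panels.

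The AAV libraries asked the same question for Kiss1 neurons that were given the tag as adults by injection into 1 nucleus (n = 4 libraries a side). In AAV ARC IP Tac2 was at log2 fold change 2.57 ± 0.62, adjusted p = 0.0241, 257 ± 331 against 33.6 ± 12.3 CPM. Pdyn was at log2 fold change 1.28 ± 0.3, adjusted p = 0.00957, 122 ± 60.6 against 49.4 ± 8.46 CPM, and Esr1 at log2 fold change 1.68 ± 0.34, adjusted p = 0.00465, 79.8 ± 60.7 against 24.1 ± 9.09 CPM. Kiss1 was at 1.41 ± 2.41 against 0.16 ± 0.229 CPM and did not pass (2.37 ± 1.28, adjusted p = 0.238). Rpl22 (chromosome 4, 152325742 to 152334071), which the virus carries, was at log2 fold change 1.18 ± 0.13, adjusted p = 1.64e-05, 198 ± 68.2 against 85.1 ± 21.5 CPM. Th and Slc32a1 rose less (0.74 to 0.85, adjusted p from 0.00723 to 0.0341). The core list had 3 of 7 higher over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0188, adjusted p = 0.333 with an estimated correlation). The KNDy list had 4 of 7 higher over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.146 with an estimated correlation).

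Hcfc1 (chromosome X, 73942792 to 73966357), a coregulator of transcription, had the largest rise in AAV ARC IP, at log2 fold change 4.82 ± 0.39, adjusted p = 4.23e-06, 6487 ± 5200 against 190 ± 29.6 CPM. Unc13b, Etl4, Unc13a, Sptb and the diacylglycerol kinase gene Dgkb followed (1.99 to 3.43, adjusted p from 7.06e-07 to 0.00786). The NMDA receptor gene Grin1 and the dendritic gene Map2 rose (0.78 to 1.34, adjusted p from 1.64e-05 to 0.00293). Ionotropic glutamate receptors had 4 higher and 1 lower of 12 over all genes, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.293 with an estimated correlation). Pan-neuronal genes had 3 of 10 higher over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.151 with an estimated correlation). The vessel genes Vtn, Rgs5, Mgp and Abcb1a fell (-4.17 to -3.45, adjusted p from 1.54e-06 to 0.000706), and the endothelial list had 7 of 8 lower over all genes and 8 adjusted over the list alone (camera adjusted p = 4.32e-07, adjusted p = 0.0148 with an estimated correlation). Cga, the alpha subunit of pituitary hormones, fell (-4.08 ± 0.63, adjusted p = 0.000631), and pituitary genes had 2 of 5 lower over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00632, adjusted p = 0.0919 with an estimated correlation). The glial genes Gja1, Slc1a3, Mal, Ctss and Itgam and the peptide genes Pmch and Cck fell (-2.86 to -1.98, adjusted p from 9.82e-08 to 0.000136). Tanycyte and ependymal markers had 6 of 9 lower over all genes and 6 adjusted over the list alone (camera adjusted p = 1.39e-07, adjusted p = 0.0115 with an estimated correlation).

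Of 14939 genes, 1097 were higher and 1065 lower in AAV ARC IP. The count of 2162 was 1390 without AAV female ARC input replicate 1, 3247 without male ARC IP replicate 2, and 1171 and 1234 without male ARC input replicate 1 or 2. It was 269 with all 40 libraries in a fit, where Th, Slc32a1, Mgp, Cga, Gja1 and Itgam did not pass (adjusted p from 0.0971 to 0.381). Named calls that ended in leave-one-out runs were Tac2 (4 of 8, up to 0.105), Pdyn (2 of 8, up to 0.0581), Th (6 of 8, up to 0.176) and Unc13a (1 of 8, up to 0.0535). On FPKM that of Th (0.0594) ended.

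AAV AVPV IP carried Kiss1 above input in all 4 of its libraries, at log2 fold change 3.78 ± 0.89, adjusted p = 0.0102, 6.13 ± 5.58 against 0.316 ± 0.22 CPM (n = 4 libraries a side). Esr1 was at log2 fold change 1.99 ± 0.34, adjusted p = 0.00176, 104 ± 38.3 against 27.2 ± 10.1 CPM, and Th at log2 fold change 1.67 ± 0.27, adjusted p = 0.000552, 45.5 ± 28.2 against 13.2 ± 2.92 CPM. Pgr, Penk, Gal and Slc18a2 rose by less (0.74 to 0.96, adjusted p from 0.00345 to 0.0479). The core list had 6 of 7 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 0.000142, adjusted p = 0.187 with an estimated correlation). The AVPV list had 7 of 11 higher over all genes and 8 adjusted over the list alone (camera adjusted p = 3.51e-06, adjusted p = 0.146 with an estimated correlation). Hcfc1, the transcription factors Skor2 and Eomes, Tnxb, Unc13b, Grin1 and Rpl22 were higher (0.85 to 4.18, adjusted p from 3.42e-06 to 0.00572). Markers of vessels, glia and other neurons fell: Dcn, Ly6a, Vtn, Cldn11, Gja1, Mal, Ctss, Cspg4 and Pmch (-4.54 to -1.74, adjusted p from 2.04e-07 to 9.84e-05).

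In AAV AVPV IP 859 genes were higher and 838 lower. The count of 1697 was 935 without AAV female AVPV IP replicate 1, 934 and 1075 without female AVPV input replicate 1 or 2, 907 without male AVPV IP replicate 2, and 1098 without male AVPV input replicate 1. It was 205 with all 40 libraries in a fit, where Kiss1, Gal, Penk, Slc18a2, Skor2, Eomes, Ly6a, Vtn, Gja1 and Cspg4 did not pass (adjusted p from 0.0712 to 0.619). Named calls that ended in leave-one-out runs were Gal (7 of 8, up to 0.382) and Penk (1 of 8, up to 0.075), and on FPKM that of Gal (0.101).

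Next, IP of the nuclei was compared within RiboTag mice (intact females and males, n = 4 libraries a side). Relative to ARC, AVPV IP had less Tac2, at log2 fold change -4.88 ± 0.52, adjusted p = 0.000342, 18.6 ± 9.73 against 579 ± 250 CPM, and less Pdyn, at log2 fold change -3.86 ± 0.32, adjusted p = 0.000105, 35.2 ± 17.9 against 462 ± 104 CPM. Tacr3 and Nhlh2 were lower as well (-4.47 to -4, adjusted p from 0.000187 to 0.00405). Gal was higher in AVPV, at log2 fold change 2.92 ± 0.46, adjusted p = 0.00768, 87.7 ± 27.2 against 12.3 ± 6.59 CPM, and so was Penk, at log2 fold change 2.23 ± 0.34, adjusted p = 0.00586, 490 ± 94.1 against 110 ± 50.4 CPM. Kiss1 stood at 5.74 ± 4.71 against 2.41 ± 2.16 CPM and did not pass (1.22 ± 0.92, adjusted p = 0.894). The glutamate transporter Slc17a6 was lower in AVPV, at log2 fold change -2.42 ± 0.26, adjusted p = 0.000342, 123 ± 23.6 against 657 ± 113 CPM. The GABA genes Gad2 and Slc32a1 were higher (1.4 to 1.79, adjusted p from 0.000342 to 0.0324). The KNDy list had 5 of 7 lower over all genes and 5 adjusted over the list alone (camera adjusted p = 7.11e-11, adjusted p = 0.035 with an estimated correlation). The glutamate neuron list had 3 of 7 lower over all genes and 4 adjusted over the list alone (camera adjusted p = 9.22e-05, adjusted p = 0.0327 with an estimated correlation). The GABA neuron list had 3 of 8 higher over all genes and 8 adjusted over the list alone (camera adjusted p = 7.11e-11, adjusted p = 0.0327 with an estimated correlation).

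Regional transcription factors separated the IP of the nuclei. Lhx8 (chromosome 3, 154306294 to 154330659) was at 40.9 ± 12.3 CPM in AVPV and had no count in ARC, so it was at least 710-fold higher (adjusted p = 0.000145). AI606473 was at least 210-fold and Gbx2 at least 126-fold higher (adjusted p = 0.00475 and 0.022). Lhx6 and Zic1 were higher too (4.54 to 7.73, adjusted p from 0.00132 to 0.0368), as was Nts, for neurotensin (3.99 ± 0.71, adjusted p = 0.0183). Bsx was at least 360-fold and Nr5a1 at least 147-fold lower in AVPV, where neither had a count (adjusted p = 0.00174 and 0.0133). Crabp1 was 455-fold lower (exact interval 81.3 to 18000, adjusted p = 0.0344). Tbx3 (chromosome 5, 119670669 to 119684724) was at log2 fold change -7.34 ± 0.7, adjusted p = 0.000187, 1.97 ± 2.66 against 219 ± 25.2 CPM. Inhbb, Lhfpl1, the dopamine transporter Slc6a3, Ghsr, Adcyap1 and Prlr were lower (-7.99 to -1.3, adjusted p from 0.000193 to 0.0459), while Esr1, which DESeq2 called (0.0039), and Pgr did not pass (-0.88 to -0.78, adjusted p from 0.0695 to 0.323). The tuberal list had 0 higher and 5 lower of 10 over all genes, and 1 and 7 adjusted over the list alone (camera adjusted p = 7.11e-11, adjusted p = 0.0327 with an estimated correlation). The preoptic and telencephalic list had 4 of 8 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 1.64e-16, adjusted p = 0.00326 with an estimated correlation). The tachykinin list had 2 of 4 lower over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00191, adjusted p = 0.0565 with an estimated correlation).

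Of 15741 genes, 21 were higher and 46 lower in RiboTag AVPV IP than in ARC IP. The count of 67 was 43 and 42 without female ARC IP replicate 1 or 2 and 39 and 42 without female AVPV IP replicate 1 or 2. The share of higher genes among those called, 31.3%, was 51% with all 40 libraries in a fit, 45.1% by DESeq2, 45.7% with no filter and 42.7% without the 3 libraries with the fewest detected genes. In leave-one-out runs these named calls ended: Slc32a1 (7 of 8, up to 0.191), Gbx2 (5 of 8, up to 0.131), Zic1 (7 of 8, up to 0.274), Nr5a1 (4 of 8, up to 0.0836), Crabp1 (7 of 8, up to 0.246), Prlr (7 of 8, up to 0.25), Nts (3 of 8, up to 0.162) and Ghsr (4 of 8, up to 0.113). On FPKM those of Gbx2 (0.114) and Prlr (0.332) ended, and with RLE scaling that of Prlr (0.0601).

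In AAV IP the region comparison (n = 4 libraries a side) again had Penk higher in AVPV, at log2 fold change 2.03 ± 0.2, adjusted p = 4.67e-05, 274 ± 116 against 64.8 ± 13.6 CPM, and Pdyn lower, at log2 fold change -2.56 ± 0.35, adjusted p = 0.00431, 19.8 ± 8.32 against 117 ± 57.6 CPM. Slc17a6 was lower (-1 ± 0.16, adjusted p = 0.00364) and Gad1, which makes GABA, higher (0.89 ± 0.17, adjusted p = 0.0115). Tac2 stood at 19.1 ± 4.29 against 246 ± 316 CPM and did not pass (-3.24 ± 0.9, adjusted p = 0.414), and neither did Gal, Slc32a1 and Kiss1 (0.83 to 2.29, adjusted p from 0.0501 to 0.36). DESeq2 called Tac2, Gal and Slc32a1 (0.0033 to 0.00587), and with no filter all 4 passed (Kiss1 at 0.00232, Tac2 at 2.45e-62). Samd3 was 491-fold higher (exact interval 87.7 to 19400, adjusted p = 1.7e-06). Tbr1, Lhx8, AI606473, Chat (which makes acetylcholine) and Nts were higher (3.39 to 4.86, adjusted p from 8.21e-08 to 0.00905). Tbx3, Nr5a1, Pmch, Hcrt (for orexin), Pomc, Bsx, Fezf1, Slc6a3 and Sox14 were lower (-6.06 to -2.73, adjusted p from 5.05e-09 to 0.00411). The tuberal list had 5 of 9 lower over all genes and 8 adjusted over the list alone (camera adjusted p = 4.93e-16, adjusted p = 0.0818 with an estimated correlation). Markers of other arcuate neurons had 0 higher and 3 lower of 10 over all genes, and 1 and 6 adjusted over the list alone (camera adjusted p = 0.00301, adjusted p = 0.309 with an estimated correlation). Choroid plexus markers had 1 of 5 higher over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0378, adjusted p = 0.292 with an estimated correlation).

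Of 14518 genes, 65 were higher and 119 lower in AAV AVPV IP than in ARC IP. Of 177 of these that RiboTag IP also measured, 162 (91.5%) had the same sign there. Both ways of tagging called 10 genes higher (0.0948 expected of independent lists) and 18 lower (0.358 expected). The count of 184 was 382 without AAV male ARC IP replicate 2, 86 and 112 without male AVPV IP replicate 1 or 2, and 58 with all 40 libraries in a fit. Calls of Slc17a6 and AI606473 ended without AAV male AVPV IP replicate 1 (adjusted p = 0.0502 and 0.058). That of Gad1 ended without it (0.099) or female ARC IP replicate 2 (0.0503), and those of Chat, Sox14 and Gad1 with all 40 libraries in a fit (0.0674, 0.442 and 0.0584), with Gad1 at 0.0552 on FPKM.

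**Figure D3:**
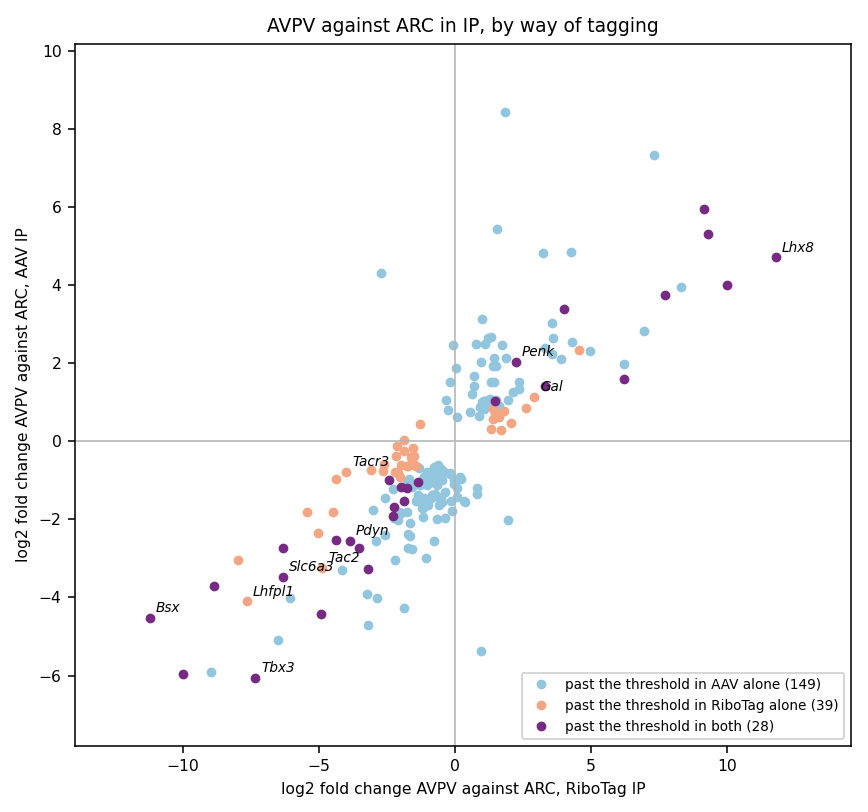
Log2 fold change of AVPV against ARC in RiboTag IP (horizontal) and AAV IP (vertical) for genes measured in both and past the threshold in at least 1 of them, with colours for AAV alone (149 genes), RiboTag alone (39) and both (28). Pdyn, Tbx3 and Bsx lie at the lower left and Penk and Lhx8 at the upper right.

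Females were compared with males in RiboTag IP (n = 2 libraries a side). In ARC the higher gene was Xist, which coats the inactive X (11 ± 1.39, adjusted p = 0.0121). The Y genes Ddx3y (at least 609-fold), Kdm5d (at least 649-fold) and Uty were lower. In AVPV these 4 were called too, with Xist at 11.5 ± 1.48, adjusted p = 0.0145, Ddx3y at least 297-fold and Kdm5d at least 281-fold lower. No gene beyond the sex chromosomes passed in edgeR's test. Kiss1 stood at 3.95 ± 1.84 against 0.866 ± 1.04 CPM in ARC (2.11 ± 1.34, adjusted p = 0.895) and 9.4 ± 3.26 against 2.07 ± 1.38 CPM in AVPV (2.16 ± 1.33, adjusted p = 1). Th stood at 235 ± 46.8 against 29.6 ± 9.08 CPM in ARC (2.99 ± 0.53, adjusted p = 0.12) and 94.8 ± 5.82 against 46.5 ± 21.7 CPM in AVPV (1.02 ± 0.5, adjusted p = 1). Slc18a2 stood in AVPV at 177 ± 19.2 against 35.4 ± 4.14 CPM (2.32 ± 0.37, adjusted p = 0.0616). Th in ARC and Slc18a2 in AVPV passed by DESeq2 (1.45e-05 and 5.78e-06) and with all 40 libraries in a fit (0.00809 and 0.0126). Both did with no filter (4.2e-07 and 0.000243), a replicate block (0.0197 and 0.0301) and without the 3 libraries of fewest genes (0.0413 and 0.0212). In simulations 59 of 147 and 45 of 139 DESeq2 calls were false. Tac2 and Esr1 in ARC (0.88 to 1.04, adjusted p from 0.886 to 0.89) and Pdyn in AVPV (1.31 ± 0.42, adjusted p = 1) did not pass. The AVPV list had 0 of 11 higher over all genes and 4 adjusted over the list alone in ARC (camera adjusted p = 0.0173, adjusted p = 0.755 with an estimated correlation). The dopamine list had 0 of 8 higher over all genes and 1 adjusted over the list alone in AVPV (camera adjusted p = 0.00276, adjusted p = 0.504 with an estimated correlation). The sex chromosome list had 1 higher and 3 lower of 5 over all genes, and 1 and 4 adjusted over the list alone in ARC (camera adjusted p = 3.61e-10, adjusted p = 0.12 with an estimated correlation).

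In each nucleus 1 gene was higher and 3 were lower of 15741, with 812 genes in ARC and 598 in AVPV at unadjusted p under 0.05, and 52 and 26 adjusted calls by DESeq2. Leaving out any of the 4 libraries of either comparison left 2 genes and ended the call of Xist (adjusted p = 0.171 to 0.33 in ARC, 0.186 to 0.408 in AVPV). On FPKM the AVPV call of Kdm5d ended (0.143). The sex effect of AVPV minus that of ARC was tested as an interaction. In it 0 genes passed in edgeR, with 546 at unadjusted p under 0.05 and 10 by DESeq2. Th had -1.96 ± 0.7, adjusted p = 1 and Pdyn 1.31 ± 0.58, adjusted p = 1.

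In AAV IP the sex comparison (n = 2 libraries a side) called 0 higher and 4 lower genes in ARC, the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty. In AVPV it called 0 higher and 5 lower, these 4 and Greb1. At unadjusted p under 0.05 there were 997 genes in ARC and 153 in AVPV, and DESeq2 called 11 and 9. Ddx3y was lower in females by 2840-fold in ARC (exact interval 509 to 112000) and by at least 758-fold in AVPV. Eif2s3y was lower by at least 240-fold in ARC and by 320-fold in AVPV (exact interval 88.1 to 2650). Greb1 (chromosome 12, 16670615 to 16800886), a gene that responds to sex steroids, was at log2 fold change -2.7 ± 0.43, adjusted p = 0.0359, 3.17 ± 1.51 against 21.6 ± 0.382 CPM. Kiss1 stood at 10.2 ± 3.16 against 1.52 ± 0.556 CPM in AVPV (2.74 ± 0.98, adjusted p = 1). In ARC it stood at 2.47 ± 3.29 against 0.233 ± 0.329 CPM (3.42 ± 1.3, adjusted p = 0.708), where 86 counts in females against 3 in males are a ratio of 14.5 (exact interval 4.79 to 71.6) by counting error alone. Th and Rpl22 in ARC (0.65 to 0.88, adjusted p from 0.683 to 0.716) and Th and Gal in AVPV (1.25 ± 0.38 and -1.28 ± 0.37, both adjusted p = 1) did not pass. With no filter Kiss1 passed in both nuclei, as did Rpl22 in ARC and Th and Gal in AVPV (0.0197 to 0.0324). In ARC the AVPV list had 0 of 11 higher over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000267, adjusted p = 0.526 with an estimated correlation). The interferon list had 0 of 9 higher over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0242, adjusted p = 0.526 with an estimated correlation), and oligodendrocyte markers 0 of 10 lower over all genes and 4 adjusted over the list alone (camera adjusted p = 1.56e-05, adjusted p = 0.254 with an estimated correlation). In AVPV the KNDy list had 0 of 7 higher over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00131, adjusted p = 0.48 with an estimated correlation) and the sex chromosome list 0 higher and 4 lower of 5 over all genes, and 1 and 4 adjusted over the list alone (camera adjusted p = 2.49e-18, adjusted p = 0.0216 with an estimated correlation). Each nucleus had 9 lists called, of which 0 in ARC and 1 in AVPV held with an estimated correlation. The ARC count was 9 without AAV male ARC IP replicate 1 and 237 without replicate 2. The call of Greb1 ended without each of its libraries (adjusted p = 0.118 to 0.539), with all 40 libraries in a fit and on FPKM (both 1).

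Castration was asked of RiboTag males (n = 2 libraries a side). In ARC IP of castrated males 4 genes were higher and 1 lower of 15741. Peg10 (chromosome 6, 4747306 to 4760517), an imprinted gene, was at log2 fold change 2.48 ± 0.31, adjusted p = 0.0105, 5004 ± 1160 against 895 ± 211 CPM. Dgkk (chromosome X, 6779306 to 6948363), a diacylglycerol kinase, was at log2 fold change 3.34 ± 0.48, adjusted p = 0.0325, 3709 ± 2010 against 367 ± 182 CPM. Pcsk1 (chromosome 13, 75089826 to 75134861), a protease that cuts peptide precursors, was at log2 fold change 3.01 ± 0.45, adjusted p = 0.0416, 497 ± 271 against 61.8 ± 15.3 CPM. Tacr3 was at log2 fold change 3.3 ± 0.52, adjusted p = 0.0497, 516 ± 163 against 52.5 ± 7.75 CPM. The lower one was the unnamed model 6330403A02Rik (-2.91, adjusted p = 0.0105, named after its values were seen). Kiss1 stood at 24.2 ± 15.8 against 0.866 ± 1.04 CPM (log2 fold change 4.72 ± 1.48, adjusted p = 0.283), Tac2 at 1571 ± 929 against 379 ± 167 CPM (2.05 ± 0.65, adjusted p = 0.284) and Pdyn at 1156 ± 487 against 462 ± 165 CPM (1.32 ± 0.41, adjusted p = 0.282). Pgr stood at 84.4 ± 10.4 against 240 ± 114 CPM (-1.51 ± 0.34, adjusted p = 0.151). None of these passed over all genes, nor did Gal, Th, Esr1 or the myelin gene Mog (-5.81 to 1.58, adjusted p from 0.218 to 0.393). The KNDy list had 1 of 7 higher over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00531, adjusted p = 0.784 with an estimated correlation). Core genes of Kiss1 neurons had 1 higher and 0 lower of 7 over all genes, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.00908, adjusted p = 0.784 with an estimated correlation). Oligodendrocyte markers had 0 of 10 lower over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00318, adjusted p = 0.784 with an estimated correlation).

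The ARC count of 5 (1881 genes at unadjusted p under 0.05) was 563 by DESeq2 and 786 with all 40 libraries in a fit. The share of higher genes among those called, 80%, was 48.5% by DESeq2, 48.6% with all 40 libraries in a fit, 46.7% with no filter and 47.8% on FPKM. DESeq2 called Kiss1 (0.00539), Tac2 (0.0238), Pgr (0.0059) and Mog (0.00104), but 78 of its 176 calls were false in simulated data of this comparison, against 5 of 69 in edgeR. With no filter Tac2 (2.06e-05), Pdyn (0.0229), Pgr (0.0164) and Mog (0.00543) passed, and with all 40 libraries in a fit Pgr (0.00546) and Mog (0.00173). Without castrated male ARC IP replicate 1 Kiss1, Tac2, Pdyn, Gal and Mog passed (0.0179 to 0.0397). It was 0 and 1 without male ARC IP replicate 1 or 2, and 1482 and 3 without castrated male ARC IP replicate 1 or 2. Each of the 4 named calls ended without male ARC IP replicate 1 (adjusted p from 0.0628 to 0.0889) or 2 (0.229 to 0.252). Those of Tacr3, Dgkk and Pcsk1 also ended without castrated male ARC IP replicate 2 (0.122, 0.0608 and 0.122), the library with the fewest detected genes.

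In AVPV IP castration gave 0 higher and 0 lower genes in edgeR, with 225 at unadjusted p under 0.05 and 5 by DESeq2. Kiss1 stood at 0.268 ± 0.379 against 2.07 ± 1.38 CPM (-3.07 ± 1.54, adjusted p = 1). Its 3 counts in castrated against 34 in intact males are an 11.2-fold lower level (exact interval 3.51 to 56.8) by counting error alone. Gal stood at 18.3 ± 12.3 against 76.6 ± 37.3 CPM (-2.06 ± 0.62, adjusted p = 1), Pgr at 87.5 ± 5.7 against 160 ± 20.5 CPM (-0.87 ± 0.34, adjusted p = 1) and Tacr3 at 13.1 ± 9.23 against 3.17 ± 0.898 CPM (2.04 ± 0.54, adjusted p = 1). Core genes of Kiss1 neurons had 0 higher and 0 lower of 7 over all genes, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.476). The effects of castration in the nuclei were then compared as an interaction, in which 0 genes were higher and 1 lower (1096 at unadjusted p under 0.05, 95 by DESeq2). The called gene was Igfbp2 (chromosome 1, 72824503 to 72852474), which binds insulin-like growth factors (adjusted p = 0.0472). It was at least 355-fold higher in castrated than in intact ARC IP and at least 28.5-fold lower in AVPV IP, with no count on the lower side of either. Kiss1 (-7.79 ± 2.12, adjusted p = 0.635) and Gal (-3.64 ± 0.88, adjusted p = 0.575) did not pass over all genes, and passed adjusted over the list alone of 13 core genes (adjusted p = 0.0159 and 0.0124). Over all genes both passed by DESeq2 (0.0103 and 0.0128) and with no filter (0.0375 and 0.0035), and Gal with all 40 libraries in a fit (0.0137). In simulated data with equal spread in all groups, 39 of 91 DESeq2 calls of this interaction were false, and 2 of 38 in edgeR. The call of Igfbp2 ended without either male ARC IP library (adjusted p = 0.194 each), either male AVPV IP library (0.068 and 0.103) or either castrated AVPV IP library (0.312 and 0.257). The count of 1 was 550 without castrated male ARC IP replicate 1, where Kiss1 (0.036) and Gal (0.0152) passed.

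**Figure D4:**
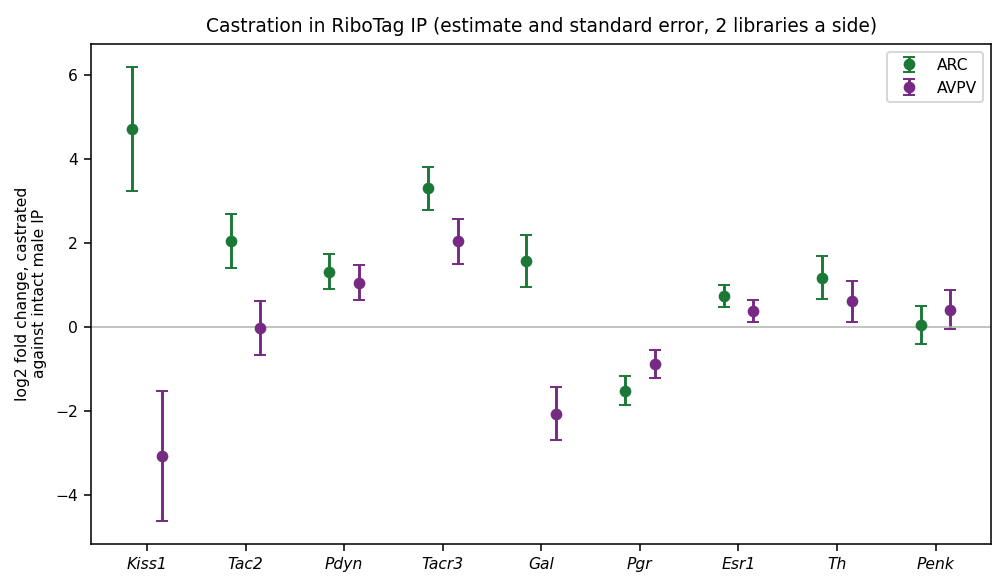
Log2 fold change of castrated against intact males in RiboTag IP of ARC (green) and AVPV (purple) for 9 genes, with points for the estimate and bars for the standard error, from 2 libraries a side. Kiss1 lies at 4.72 in ARC and -3.07 in AVPV and Gal at 1.58 and -2.06, and of all points only Tacr3 in ARC passed over all genes.

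Input libraries show the tissue without the pull-down (n = 4 libraries a side for region, 2 for sex and castration). AVPV input had more Gad2, at log2 fold change 1.19 ± 0.08, adjusted p = 4.15e-05, 2149 ± 214 against 946 ± 159 CPM, and more Gad1, Slc32a1 and Penk (1.44 to 1.53, adjusted p from 0.00118 to 0.00448) than ARC input. Slc17a6, Cartpt, Pomc, Tbx3, Nr5a1, Fndc3c1, Pmch and Parpbp were lower (-9.56 to -1.68, adjusted p from 0.000135 to 0.0261). Lhx8 was at least 501-fold and AI606473 at least 106-fold higher, Slc18a3 469-fold (exact interval 83.5 to 18600) and Vip 167-fold (exact interval 45.7 to 1390). Zic4 was higher (7.43 ± 1.03, adjusted p = 0.00532), and Pdyn did not pass (-1.05 ± 0.25, adjusted p = 0.0773), but did by DESeq2 (0.00208). The GABA neuron list had 4 of 8 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 6.09e-08, adjusted p = 0.0095 with an estimated correlation). The tuberal list had 4 of 9 lower over all genes and 5 adjusted over the list alone (camera adjusted p = 8.86e-10, adjusted p = 0.00739 with an estimated correlation). Of 15329 genes, 87 were higher and 69 lower. The count of 156 was 44 and 32 without female ARC input replicate 1 or 2, 1283 without male ARC input replicate 1, 40 and 38 without female AVPV input replicate 1 or 2, and 37 and 39 without male AVPV input replicate 1 or 2. In leave-one-out runs these named calls ended: AI606473 (4 of 8, up to 0.0962), Slc18a3 (5 of 8, up to 0.141), Zic4 (1 of 8, up to 0.0523), Vip (6 of 8, up to 0.189), Pmch (2 of 8, up to 0.0522), Nr5a1 (5 of 8, up to 0.153), Fndc3c1 (6 of 8, up to 0.11) and Slc32a1 (1 of 8, up to 0.0523).

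By sex, ARC input had 5 higher and 8 lower genes in females. Xist (8.43 ± 1.12, adjusted p = 0.0133), Tmem177 (99.1-fold, exact interval 33.5 to 484, adjusted p = 0.0182), the peptide-processing gene Cpe and Itm2c (1.11 to 1.31, adjusted p from 0.0287 to 0.038) were higher. The Y genes Kdm5d and Ddx3y were lower, by at least 316-fold and 312-fold. The long noncoding Snhg11 and Malat1, Leng8 and Pwwp2a were lower by less (-1.64 to -0.81, adjusted p from 0.0118 to 0.0362). AVPV input had 3 higher and 6 lower genes. Rps27 was 233-fold higher (exact interval 79.5 to 1130, adjusted p = 0.00185), and Xist 6740-fold (exact interval 1870 to 55700). Meg3 and Pwwp2a were lower (-1.21 to -0.99, adjusted p from 0.00185 to 0.0257), and Kdm5d and Ddx3y at least 281-fold and 150-fold lower. Castration called 3 genes in ARC input. Tmem177 was 119-fold higher (exact interval 40.5 to 581, adjusted p = 0.031) and Kcnab3 at least 38.3-fold lower (adjusted p = 0.031). The unnamed model Gm9855 was the third (higher, adjusted p = 0.031, named after its values were seen). In AVPV input it called Rps27 (384-fold higher, exact interval 131 to 1860, adjusted p = 0.00155). Tacr3 in castrated ARC input stood at 29.6 ± 12.8 against 5.05 ± 2.86 CPM (2.55 ± 0.68, adjusted p = 0.156), and passed by DESeq2 (0.00295) and with all 40 libraries in a fit (0.00699). Rps27 and Tmem177 also differed as widely between the 2 libraries of male ARC IP, at 0.133 and 51.1 CPM and at 28 and 0.225 CPM. These folds cannot be put down to sex or castration alone, and how the authors' software assigned fragments to them was not tested. RiboTag female input held 0.96% to 1.1% ribosomal protein RNA and male 0.74% to 0.8%, so other autosomal sex calls may reflect the libraries.

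In these 4 comparisons of input DESeq2 called 669, 96, 1029 and 3 genes, against 13, 9, 3 and 1. In ARC input the sex count was 2 without either female library and 1994 without male replicate 1. The castration count there was 1972 without male replicate 1 and 695 without castrated replicate 2. The AVPV sex count was 4 and 3 without female input replicate 1 or 2 and 5 and 4 without male input replicate 1 or 2, and the AVPV castration count was 0 without either male library. Apart from Kdm5d and Ddx3y in both nuclei and Rps27 in the AVPV sex comparison, every named call of these comparisons ended without at least 1 library, at adjusted p up to 0.77. With all 40 libraries in a fit Snhg11 (0.225) and Malat1 (0.178) in ARC and Rps27, Pwwp2a and Meg3 in AVPV (0.397, 0.397 and 0.733) did not pass by sex, nor Rps27 by castration (1). On FPKM 5 calls of the ARC sex comparison (Tmem177, Cpe, Leng8, Snhg11 and Malat1, 0.0645 to 0.0919), Pwwp2a and Ddx3y in AVPV (0.104 each) and Tmem177 (0.0715) and Kcnab3 (0.119) by castration ended.

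Finally, AAV IP was set against RiboTag IP of intact mice (n = 4 libraries a side). These ways of tagging also differ in mice, injection and preparation, which cannot be separated. In ARC Rpl22 was higher in AAV IP, at log2 fold change 3.17 ± 0.29, adjusted p = 7.67e-06, 185 ± 63.8 against 20.3 ± 7.4 CPM. Esr1 was lower, at log2 fold change -2.03 ± 0.32, adjusted p = 0.00204, 74.6 ± 56.8 against 293 ± 108 CPM, and so was Pdyn, at log2 fold change -2.06 ± 0.34, adjusted p = 0.00308, 114 ± 56.5 against 466 ± 110 CPM. Prlr, Pgr, Tacr3 and the oxytocin receptor Oxtr were lower too (-2.69 to -1.58, adjusted p from 0.000547 to 0.00948), while Kiss1 and Tac2 did not pass (-1.63 to -1.32, adjusted p from 0.176 to 0.552), though Tac2 did with no filter (4.32e-10). The core list had 4 of 7 lower over all genes and 4 adjusted over the list alone (camera adjusted p = 3.72e-05, adjusted p = 0.265 with an estimated correlation). The KNDy list had 3 of 7 lower over all genes and 6 adjusted over the list alone (camera adjusted p = 4.69e-06, adjusted p = 0.199 with an estimated correlation). The other neuropeptide list had 5 higher and 1 lower of 12 over all genes, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.000193, adjusted p = 0.0744 with an estimated correlation), with Hcrt, Oxt and Trh higher (3.96 to 8.13, adjusted p from 0.00215 to 0.00586). Acan, Meis2, Chrm2, Metrn, Gad2, Map2 and Mbp were also higher (1.1 to 7.3, adjusted p from 0.00204 to 0.0247). Fam131c, Lhfpl1, Papolb, Creb3l1 and P4ha3 were lower (-5.84 to -2.68, adjusted p from 0.0103 to 0.0175).

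Of 16081 genes, 261 were higher and 210 lower in AAV than in RiboTag ARC IP. The count of 471 was 173 and 101 without RiboTag female ARC IP replicate 1 or 2, 211 and 110 without AAV female ARC IP replicate 1 or 2, and 168 without either AAV male ARC IP library. It was 800 without RiboTag male ARC IP replicate 1. In leave-one-out runs these named calls ended: Acan (5 of 8, up to 0.105), Chrm2 (1 of 8, up to 0.0588), Metrn (7 of 8, up to 0.151), Fam131c (5 of 8, up to 0.0908), Lhfpl1 (3 of 8, up to 0.112), Papolb (2 of 8, up to 0.0807), Creb3l1 (5 of 8, up to 0.139), P4ha3 (5 of 8, up to 0.0963) and Tacr3 (2 of 8, up to 0.081). On FPKM Acan did not pass (0.051).

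AAV AVPV IP also had more Rpl22 than RiboTag AVPV IP, at log2 fold change 2.95 ± 0.29, adjusted p = 3.44e-05, 139 ± 22.9 against 18 ± 2.92 CPM. Kiss1 stood at 5.74 ± 5.21 against 5.86 ± 4.81 CPM (-0.22 ± 0.91, adjusted p = 0.974) and, like Esr1 (-0.68 ± 0.3, adjusted p = 0.364), did not pass. Hcfc1 was higher, at log2 fold change 3.41 ± 0.36, adjusted p = 7.42e-05, 3099 ± 1330 against 292 ± 56.9 CPM. Ptprz1, Bdnf, Cryab, Adcyap1, Map2, Mbp and the RNase P RNA Rpph1 were higher (1.1 to 4.17, adjusted p from 0.00238 to 0.0177). Cck, Gabra2, the immediate early gene Dusp1, Pxn, Krt1, Necab3 and Rtl1 were lower (-2.97 to -1.49, adjusted p from 0.00204 to 0.0342). The AVPV list had 0 of 11 lower over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.741 with an estimated correlation). Of the genes tested, 97 were higher and 44 lower. The count of 141 was 38 and 26 without RiboTag female AVPV IP replicate 1 or 2, 83 and 89 without RiboTag male replicate 1 or 2, 89 and 36 without AAV female replicate 1 or 2, and 41 and 44 without AAV male replicate 1 or 2. Named calls of the AVPV comparison that ended in leave-one-out runs were Rpph1 (6 of 8, up to 0.146), Ptprz1 (3 of 8, up to 0.0749), Cryab (6 of 8, up to 0.14), Bdnf (2 of 8, up to 0.0639), Pxn (7 of 8, up to 0.224), Krt1 (6 of 8, up to 0.192), Necab3 (4 of 8, up to 0.08), Dusp1 (4 of 8, up to 0.0888) and Rtl1 (7 of 8, up to 0.174). On FPKM Pxn and Rtl1 did not pass (0.068 each).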

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

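Of the tests below, those of genes at least 4-fold higher in RiboTag female IP, of Gal in male ARC IP, of an input library under a wrong label and of unbound RNA in the AAV IP were chosen only after the results they bear on had been seen.

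The responses to castration were flagged as differing between nuclei in RiboTag IP for 3 genes, of which only Igfbp2 passed over all genes in edgeR. The response of AVPV minus that of ARC was -20.9 (log2) for Igfbp2 (adjusted p = 0.0472 over all genes), -7.79 for Kiss1 and -3.64 for Gal, the last 2 past the threshold in edgeR adjusted over the list alone of 13 core genes (0.0159 and 0.0124), and over all genes by DESeq2 (0.0103 and 0.0128), of whose calls 39 of 91 were false in simulated data of this interaction. For Igfbp2, which is absent from 4 of the 8 libraries, this is a fitted value and no bound. Its level was 73.4 and 26.3 CPM in castrated ARC IP, 0 in both male ARC IP libraries, 4.08 and 7.42 CPM in male AVPV IP and 0 in both castrated AVPV IP libraries, and its call ended without any of the last 6 (adjusted p from 0.068 to 0.312).

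A stronger pull-down from the castrated ARC pools would raise strongly enriched genes alike. The 15 genes at least 4-fold higher in RiboTag female ARC IP than in input had a median of 0.677 (quartiles -0.515 to 1.24). Kiss1 rose by 4.72 ± 1.48. It was enriched by 6.55 in RiboTag ARC and these genes by a median of 3.06 in females, so they cannot exclude a stronger pull-down. For the 1.58 ± 0.614 of Gal it needs Gal above input in intact male ARC IP. There -0.069 ± 0.584 goes against it but, by its spread, does not exclude it. Only 4 strongly enriched genes were there in AVPV (median 0.121), and the genes called in AAV IP, which had been chosen beforehand (castration medians -0.117 in ARC and -0.0575 in AVPV), were enriched by medians of only 0.654 and 0.66 and so decide nothing, which leaves a weaker pull-down from the castrated AVPV pools open. Without castrated male ARC IP replicate 2, which has the fewest detected genes, the Kiss1 difference was -6.87 ± 2.24 and that of Gal -2.74 ± 0.816, so that library is not the whole cause. Astrocyte, oligodendrocyte and microglial markers had medians of -1.02, -1.09 and -1.17 in castrated ARC IP and of -0.98, -0.295 and -0.413 in castrated AVPV IP, so a purer pull-down could add to the rise in ARC. Punch position and other differences between the pools were not tested, so the cause stays open, and opposite regulation of Kiss1 by testosterone in the nuclei is only a hypothesis that rests on 2 pools a group and that these data cannot decide.

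In AAV male ARC IP replicate 1, Kiss1 neuron genes were near their input level: the 12 genes of the core and KNDy lists had a median log2 ratio to input of 0.156, against 0.93 in replicate 2. If an input library stood under this label, glial, microglial and vessel markers would lie near 0, but the 44 markers had a median of -2.28 (-1.22 in replicate 2). The 859 genes that AAV AVPV IP enriches had a median of 0.527, 90.1% above 0 (0.531 in replicate 2). A fully failed pull-down would leave both sets near 0, which these values argue against, but a partial failure stays open. The 22 markers of other hypothalamic neurons had a median of -1.17 (-0.963 in replicate 2) but went both ways, with Crh at 1.63, Th at 0.902, Trh at 0.77 and Oxt at 0.711, against 0.0394, -0.0448, -0.324 and -1.98 in replicate 2, so the median, set as the bound beforehand, cannot exclude RNA from some of these neurons. That, neurons outside the lists and few infected Kiss1 cells stay open. The tagged Rpl22 was at 1.13 (0.97 in replicate 2).

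In AAV ARC IP, 12 neuropeptide genes of other hypothalamic neurons had a median log2 fold change of 1.78 over RiboTag ARC IP. More unbound RNA in the AAV IP would raise glial, vessel and tanycyte markers alike. The 52 markers went both ways (median 0.272, endothelial -0.662, oligodendrocyte 0.589) and cannot exclude it. In AAV against RiboTag ARC input the same 12 genes had a median of 1.22, with 75% above 0 and only Hcrt (4.78, adjusted p = 0.00238) and Vip (5.25, adjusted p = 0.0391) past the threshold, which is in line with punches that took in other tissue. The way of tagging and the punches cannot be separated by this design, and a biological difference between the mice was not tested.

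Other splits of the same libraries were tested for each comparison of at least 4 libraries a side, with fits of only 2 groups, so the counts differ from those above. The real split was the only 1 of 50 drawn splits to call as many genes for IP against input in RiboTag ARC (371, highest other 1) and AVPV (992, highest other 0). It was the only 1 of 35 in AAV ARC (1787, highest other 5) and AVPV (2084, highest other 6), for AVPV against ARC in RiboTag IP (123, highest other 7), AAV IP (176, highest other 5) and RiboTag input (80, highest other 30), and for AAV against RiboTag in ARC IP (575, highest other 5) and AVPV IP (723, highest other 6). So few splits cannot exclude chance. Sex and castration, with 2 libraries a side, allow too few splits for such a test.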

How the results depend on the processing

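Of 290 gene values named in the report, 238 passed the threshold, and none of these turned its sign under any alternative. All 238 stayed past it with no filter and 237 with RLE factors; DESeq2, which gave 2 genes no adjusted p, kept all 237 it tested. Limma on FPKM kept 217 and all 40 libraries in a fit 212. The alternative without the 3 libraries with the fewest detected genes, chosen after seeing the data, kept 158 of 165, and the comparisons within AAV libraries have no value under it because their fit holds no such library. Over 1988 leave-one-out values 1672 stayed past the threshold. Where a left-out library leaves a group with 1, that lone library is assumed to vary like the other groups. With 2 libraries a group, 4-fold changes in castrated ARC IP were recovered in 27.1% of cases in simulated data, whose groups share 1 spread. Kiss1 reached 37.2 CPM at most, so depth limits its folds. For the counts below, with the main count in brackets, the cause was not tested beyond what each setting changes by construction.

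With all 40 libraries in a fit, counts were 2808 for IP against input in RiboTag ARC (1244), 1060 for RiboTag AVPV (407), 269 for AAV ARC (2162) and 205 for AAV AVPV (1697). Others were 349 for region in RiboTag IP (67) and 58 in AAV IP (184). Sex gave 44 in RiboTag ARC IP (4) and 28 in AVPV IP (4). Then came 786 for castration in ARC IP (5), 2 for the sex interaction (0), 110 for the castration interaction (1) and 340 for region in input (156). Next were 373 for sex in ARC input (13) and 5 in AVPV input (9). Castration gave 834 in ARC input (3) and 0 in AVPV input (1). Last came 854 for AAV against RiboTag in ARC (471) and 418 in AVPV (141). DESeq2 gave 2144 for IP against input in RiboTag ARC (1244), 837 for RiboTag AVPV (407), 264 for region in RiboTag IP (67) and 309 for region in AAV IP (184). It also gave 52 for sex in RiboTag ARC IP (4) and 26 in AVPV IP (4). Castration gave 563 in ARC IP (5) and 5 in AVPV IP (0). Then came 11 for sex in AAV ARC IP (4), 9 for sex in AAV AVPV IP (5), 10 for the sex interaction (0) and 95 for the castration interaction (1). Next were 498 for region in input (156), 669 for sex in ARC input (13), 96 for sex in AVPV input (9) and 1029 for castration in ARC input (3). Last came 3 for castration in AVPV input (1), 1161 for AAV against RiboTag in ARC (471) and 600 in AVPV (141).

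With no filter, counts were 730 for RiboTag AVPV (407), 234 for region in RiboTag IP (67), 425 for region in AAV IP (184) and 32 for sex in RiboTag ARC IP (4). No filter also gave 48 for sex in RiboTag AVPV IP (4) and 116 in AAV ARC IP (4). Castration gave 319 in ARC IP (5) and 10 in AVPV IP (0). Then came 23 for sex in AAV AVPV IP (5), 16 for the sex interaction (0), 78 for the castration interaction (1) and 489 for region in input (156). Next were 431 for sex in ARC input (13) and 56 in AVPV input (9). Castration gave 725 in ARC input (3) and 7 in AVPV input (1). Last came 945 for AAV against RiboTag in ARC (471) and 515 in AVPV (141). Limma on FPKM gave 109 for region in AAV IP (184) and 103 in input (156). For castration it gave 23 in ARC IP (5), 1 in AVPV IP (0), 20 in ARC input (3) and 3 in AVPV input (1). Without the 3 libraries with the fewest detected genes, counts were 1022 for RiboTag AVPV (407), 157 for region in RiboTag IP (67), 10 for sex in RiboTag ARC IP (4) and 3 for castration in ARC IP (5). Others were 1221 for region in input (156), and for sex 854 in ARC input (13) and 276 in AVPV input (9). Castration in ARC input gave 800 (3). Then came 3 for castration in AVPV input (1), 921 for AAV against RiboTag in ARC (471) and 337 in AVPV (141). On FPKM the share of higher calls was 27.5% in RiboTag AVPV (38.8%), 39.9% in AAV ARC (50.7%) and 47.8% for castration in ARC IP (80%). In input it was 57.1% for sex in AVPV (33.3%) and 40% for castration in ARC (66.7%). Of AAV IP against input, 64.7% in ARC (50.7%) and 64.4% in AVPV (50.6%) were higher with all 40 libraries in a fit. Of AAV against RiboTag in AVPV, 53% were higher by DESeq2 and 52.2% with no filter (68.8%). RLE factors moved no count by over 1.5 times. Of 130 calls of gene lists, 28 held with an estimated correlation.

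With a replicate block, counts were 119 for region in RiboTag IP (67), 18 for castration in ARC IP (5), 55 for region in input (156) and 0 for castration in ARC input (3). It ended 16 of 238 gene calls, among them Tac2 in AAV ARC IP against input (adjusted p = 0.106), Tacr3 (0.0541) and Ghsr (0.0851) in RiboTag AVPV IP against input, and Gbx2 (0.0759), Nr5a1 (0.0519) and Ghsr (0.0538) by region in RiboTag IP. Whether a shared number marks a shared lysate is not stated in the labels, so pairing stays open. Deviations of IP and input of the same number correlated at -0.044 to 0.0309 in RiboTag and at 0.0787 to 0.32 in AAV, with 3 of 10 pairs over 0.1, all of them AAV. Those of ARC and AVPV exceeded 0.1 in 3 of 5 pairs of IP and 0 of 3 of input, so not every pair did and the fit without a block was kept.

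Leaving out 1 library at a time, counts ranged over 628 to 2380 for IP against input in RiboTag ARC, 205 to 445 for RiboTag AVPV, 1171 to 3247 for AAV ARC and 907 to 1626 for AAV AVPV. They also ranged over 39 to 84 for region in RiboTag IP and 86 to 382 in AAV IP. Sex in RiboTag gave 2 in ARC IP and in AVPV IP. Then came 0 to 1482 for castration in ARC IP, 4 to 237 for sex in AAV ARC IP, 0 to 550 for the castration interaction and 32 to 1283 for region in input. Next were 2 to 1994 for sex in ARC input and 3 to 5 in AVPV input. Castration gave 3 to 1972 in ARC input and 0 to 1 in AVPV input. Last came 101 to 800 for AAV against RiboTag in ARC and 26 to 89 in AVPV. The values below, which did not pass, changed sign in leave-one-out runs (log2 fold change, range). In RiboTag ARC these were Gal (-0.0592, -0.36 to 0.125), Penk (0.114, -0.175 to 0.289) and Slc32a1 (0.117, -0.1 to 0.26). In RiboTag AVPV they were Tac2 (0.189, -0.363 to 0.428) and Pdyn (0.132, -0.0983 to 0.278). Kiss1 did so for sex in AAV ARC IP (3.42, -0.681 to 7.73). It also did for AAV against RiboTag in ARC (-1.32, -3.49 to 0.0287) and AVPV (-0.223, -0.51 to 0.262).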

Other observations

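All values in this part were chosen after they had been seen. Greb1, called lower in females than in males in AAV AVPV IP, stood in RiboTag AVPV IP at 6.35 ± 1.21 CPM in females, 30.6 ± 12.6 in males and 12.4 ± 3.96 in castrated males (SD, n = 2 libraries). In RiboTag ARC IP it stood at 41.4 ± 15 CPM in females, 98.6 ± 30.4 in males and 9.97 ± 0.553 in castrated males, and in ARC input at 4.29 to 8.05 CPM on average in these groups. AVPV input was also higher in AAV males (7.38 and 17.3 CPM) than in AAV females (2.81 and 2.6), and RiboTag male AVPV input stood at 21.7 and 2.6 CPM, so the difference cannot be put down to the tagged neurons alone. Greb1 did not pass over all genes in any RiboTag sex or castration comparison.

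Hcfc1 took 1220 to 13300 CPM in the AAV IP libraries, against 138 to 211 CPM in AAV input and 163 to 469 CPM in all RiboTag libraries. Its location, on chromosome X from 73942792 to 73966357, holds no part of the Kiss1 or Rpl22 genes. Whether the virus or its promoter carries matching sequence is not known from the labels.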
